A study of Mus musculus with 18 samples.

How the data were processed

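DNA copy number was measured on 18 two-colour Agilent arrays, 1 array per slide, each comparing DNA of a mouse tissue with tail DNA. Per the labels, the tissue DNA carried the Cy5 dye (the red channel) and the tail DNA the Cy3 dye (the green channel), and no array had the dyes exchanged. The arrays form 4 groups that the labels give, namely normal choroid plexus (3 arrays), Atoh1 papilloma (5), Atoh1 carcinoma (5) and Blbp carcinoma (5). The tail DNA was a mix for the normal tissue. For the tumours it came from a female or a male, and the labels do not give the sex of the tumours themselves. By the codes in the array titles, arrays shared tail DNA, and it was not matched to each tumour. All normal tissues had the same code, and papillomas and Atoh1 carcinomas had a common female and a common male code. The titles give the tail DNA of the Blbp carcinomas other codes than that of the papillomas and Atoh1 carcinomas, again shared by sex. In comparisons with Blbp carcinomas, a block for the sex of the tail reference therefore joins tail DNA of different codes.

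The deposited scanner files hold intensity values for the spots, per the file headers background subtracted, spatially detrended and dye normalised by a lowess fit within the array. The file headers name Agilent Feature Extraction 10.7.3.1 with a lowess protocol for comparative genomic hybridisation, whereas the submitters' processing notes name Agilent Feature Extraction 10.5.1.1. The same deposited files hold unnormalised median spot and local background intensity values, which were used for 1 alternative. They also hold a log10 ratio of red over green, per the file headers the software's own log ratio. The deposited value table holds a log2 ratio of tissue over tail. This scale was settled from the values, since the table equals the scanner files' log10 ratio multiplied by the base 2 logarithm of 10 within 0.001 on every array.

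The log2 ratio of the processed red over the processed green signal was computed for each spot. Control spots and spots marked as outliers by the scanner software were left out, and spots of the same probe were averaged. Each array was centred on the median of its autosomal probes. The arrays held 974016 spots each, and 963261 probes remained. Probe positions are those of build mm9, as the files give them. Medians were taken over windows of 100 kb with at least 3 probes, which left 23357 autosomal windows for testing.

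Each array was segmented alone by penalised least squares with optimal partitioning. The penalty was 3 times the logarithm of the number of windows times the noise variance, estimated from differences between neighbouring windows. A segment was called gained or lost at a mean log2 ratio of 0.2 or more in size. The altered genome share is the percent of autosomal windows inside called segments. A chromosome was called gained or lost as a whole when at least 90% of its windows were called, and in part when at least 10% were. The segmentation was tested on simulated arrays, where it called at least 97.5% of windows in simulated changes of 0.3 and at most 0.0378% of other windows. Noise there was independent between windows, and changes between 0.2 and 0.3 were not simulated. These rates need not hold on real arrays, since normal replicate 3 had 3.95% of its windows called without a called autosome. In simulated window data, limma called 99, 73, 60 and 52 of 100 windows with a difference of 0.4 in the 4 comparisons, in the order given below. It also made 9, 13, 11 and 8 false calls. The noise simulated for limma was independent too, with the same spread in both groups, which the real groups need not have.

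The plan made before the data were examined was to read the Trp53 locus from probes named after the gene. The files used here name no genes, and the gene annotation at hand is of assembly GRCm38.p6, whose positions differ from those of mm9. The deletion was therefore located without use of the groups, as the lowest running median of 5 neighbouring probes on chromosome 11 in the mean over all 18 arrays. It was extended over neighbouring probes with a mean below −0.5, and no gene was assigned to it by position. For the same reason windows were tested in place of genes, and the annotation served only to give the chromosome of each gene named.

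There were 4 comparisons, namely papilloma against normal tissue, Atoh1 carcinoma against papilloma, Blbp carcinoma against papilloma, and Blbp against Atoh1 carcinoma. The deletion and the altered genome share were compared by two-sided exact permutation tests of the difference of group means, with Benjamini-Hochberg adjustment over the 4 comparisons. The medians of the 19 autosomes and the windows were compared with limma 3.58.1 in R 4.3.3 (linear model and moderated statistic), using only the groups compared. P-values were adjusted by Benjamini-Hochberg over the autosomes or the windows, and an adjusted p under 0.05 was called. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Values after ± are standard deviations over arrays, and SE marks a standard error of a fitted difference. The number of arrays limits the precision.

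The items named were chosen by a rule fixed before the data were examined, except for the change from genes to windows. It took every autosome past the threshold and every autosome with a median of 0.2 or more in size in at least 3 arrays of a group. It took the 10 windows with the largest difference among those past the threshold, with at most 2 per chromosome. It took segments under 5 Mb with a mean of at least 0.5 in size, in at least 2 tumours of a group and in no normal tissue, up to 8 by number of tumours and then by size. The genes Trp53, Myc, Atoh1, Fabp7, Taf12, Nfyc and Rad54l were to be named in any case. Lists of genes were fixed at the same time. They cover choroid plexus identity, multiciliogenesis, the Myc network, the p53 pathway and other brakes on growth, growth and cell cycle drivers, the DNA damage response, spindle checkpoint and chromosome segregation, and Notch, Hedgehog, Wnt and Bmp signalling. They also cover rearranging loci of lymphocytes as markers of another cell type, the engineered loci, and 3 mouse counterparts of genes on human chromosome arm 1p. Of 194 different names, all were found, as 191 genes.

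The alternatives were normexp background correction of the median signals (offset 50), centring each array on its most frequent window value (the mode), the deposited value table, and only probes well above background. Others were all 4 groups in one fit, blocks for the replicate number, the sex of the tail reference or the scan day, leaving out each replicate, and an exact permutation test per autosome. The altered genome share was also computed at thresholds of 0.1 and 0.3, from 1 Mb bins without segmentation, and with the penalty doubled, and windows were also taken with at least 1 or 10 probes. The permutation of the deletion and the altered genome share within scan days was added after the data had been seen. The normexp correction was planned on mean spot signals and run on median ones, since the files used here hold no mean of the spots. A correction for base composition was planned and was not run, since no genome sequence was at hand. The X and Y chromosomes were left out of all tests. A count of gained and lost autosomes with mode centring was also added after the data had been seen.

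The scans fell on 4 days. The first held papilloma 1 and Atoh1 carcinomas 1, 2, 4 and 5, and the second held papillomas 2 to 5 and Atoh1 carcinoma 3. All normal tissues were scanned on a day of their own, and so were all Blbp carcinomas.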

Results

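Copy number was measured in choroid plexus, the epithelium that secretes cerebrospinal fluid, and in tumours of it, to profile gains and losses in normal tissue, papilloma and carcinoma. There were 18 arrays. Normal choroid plexus (n = 3) came from mice with MycT58A and floxed p53 alleles, for which the labels name no Cre. Papillomas (n = 5) carried MycT58A, a stabilised form of Myc, switched on by Atoh1-Cre. Atoh1 carcinomas (n = 5) carried in addition floxed p53 alleles. Blbp carcinomas (n = 5) carried MycT58A with 1 floxed and 1 deleted p53 allele and Blbp-Cre, named after the protein that Fabp7 encodes. The tissue signal was 6.83 ± 1.98 times its background in normal tissue, 9.69 ± 1.66 in papillomas, 7.53 ± 1.77 in Atoh1 carcinomas and 3.09 ± 0.35 in Blbp carcinomas (medians per array, mean ± SD over arrays). All values below are log2 ratios of tissue over tail DNA unless a percent is given.

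The first comparison asked which copy number changes accompanied papilloma. Papillomas had no gained or lost autosome, in whole or in part, in any of 5 arrays, and nor did the 3 normal tissues. Called segments covered 0.657% ± 0.302 (SD, n = 5) of the autosomal windows in papillomas (the altered genome share) and 1.74% ± 1.93 (SD, n = 3) in normal tissue. The region on chromosome 11 that was lost in carcinomas, described below, was intact in papillomas at −0.16 ± 0.07 (SD, n = 5), beside −0.22 ± 0.02 (SD, n = 3) in normal tissue. Chromosome 15, which carries Myc, had a median between −0.01 and −0.00 in all 5 papillomas.

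The altered genome share differed by −1.08 percentage points between papilloma and normal tissue (two-sided exact permutation p = 0.214, adjusted 0.222), and by 0.0231 without normal replicate 3, whose share alone was 3.95%. The deletion value differed by 0.06 (exact permutation p = 0.232, adjusted 0.310). With limma, 0 of 19 autosomes differed, and 4 had an unadjusted p under 0.05. Among windows of 100 kb, limma called 5. On chromosome 16 the window starting at 35500001 was lower in papillomas by −0.48 (SE 0.03, adjusted p = 3.61e-05), and those starting at 36300001 and 44800001 were higher by 1.29 (SE 0.14) and 0.61 (SE 0.07). The window starting at 19400001 on chromosome 8 was lower by −0.37 (SE 0.04), and that starting at 58800001 on chromosome 17 by −0.22 (SE 0.03). With probes well above background only, the difference at 36300001 on chromosome 16 was −0.06. Without normal replicate 1 or 3 the count was 2, without papilloma replicate 3 it was 9, and with all 4 groups in one fit it was 0. All normal tissues were scanned on a day of their own and had a mixed tail reference, so scan day, tail DNA and group cannot be told apart.

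**Figure D1:**
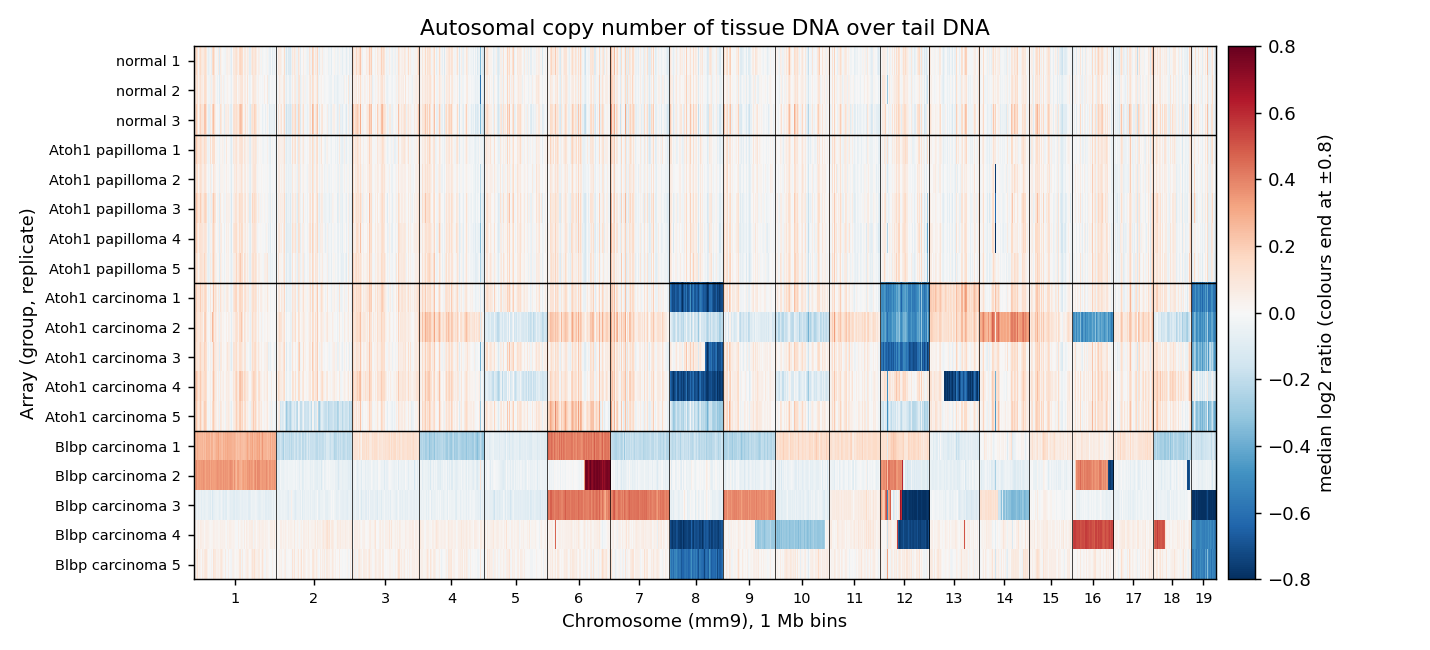
Median log2 ratio of tissue over tail DNA in bins of 1 Mb along the 19 autosomes (mm9), 1 horizontal strip per array, with colours ending at 0.8 in size. The 3 normal tissues and 5 papillomas show no called autosome, and each of the 10 carcinomas shows between 2 and 12.

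The second comparison asked what loss of p53 added to Myc in tumours of the same Cre line. In Atoh1 carcinomas whole chromosomes, or large parts of them, were lost repeatedly. Chromosome 8 was lost in whole or in part in 5 of 5 carcinomas, and chromosomes 12 and 19 in 4 of 5 each. All 3 chromosomes were lost in 4 carcinomas, whereas Atoh1 carcinoma 4 lost chromosome 8 without the others. The median of chromosome 8 was −0.39 ± 0.29 (SD, n = 5), that of chromosome 12 was −0.35 ± 0.29 and that of chromosome 19 was −0.37 ± 0.18. In papillomas the same chromosomes lay between −0.04 and 0.01.

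Losses differed in extent between tumours. Atoh1 carcinomas 1 and 4 had lost the whole of chromosome 8, with medians of −0.69 and −0.72, and Atoh1 carcinoma 3 had lost its distal part from 90.2 to 131.7 Mb (mm9) at −0.66. Chromosome 12 was lost as a whole in Atoh1 carcinomas 1, 2 and 3. Chromosome 19 was lost as a whole in Atoh1 carcinomas 1, 2, 3 and 5, with medians from −0.57 to −0.33. Single tumours had further changes, such as the loss of chromosome 16 at −0.47 and the gain of chromosome 14 at 0.32 in Atoh1 carcinoma 2, and the loss of chromosome 13 from 36.0 to 120.3 Mb in Atoh1 carcinoma 4.

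Of 191 listed genes, 20 lie on chromosomes 8, 12 or 19 in GRCm38.p6, which is 10.47% beside 11.74% of all protein-coding genes. The p53 pathway list of 22 genes includes Rbl2, a relative of the retinoblastoma gene, on chromosome 8. Of the Myc network, 4 of 18 genes lie there, namely Mycn, Max and Odc1 on chromosome 12 and Mxi1 on chromosome 19. Max encodes the partner protein of Myc, and Mxi1 encodes an antagonist. The spindle and segregation list has 2 of 21 (Smc3, Incenp on chromosome 19), the DNA damage list 2 of 24 (Lig4, Wrn on chromosome 8) and the multiciliogenesis list 2 of 15 (E2f4 on chromosome 8, Rfx3 on chromosome 19). Among growth and cell cycle drivers there are 2 of 33 (Fgfr1 on chromosome 8, Akt1 on chromosome 12), and in the Notch, Hedgehog, Wnt and Bmp list 2 of 20 (Gdf7 on chromosome 12, Sufu on chromosome 19). The choroid plexus identity list has 1 of 20 (Sostdc1 on chromosome 12), and 3 of 12 rearranging lymphocyte loci are those of the immunoglobulin heavy chain on chromosome 12. None of the 4 engineered loci or the 3 counterparts of human 1p genes lies on chromosomes 8, 12 or 19. Where a chromosome was lost in part, the position of these genes relative to the lost part was not determined.

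Among the chromosomes of the genes chosen in advance, chromosome 15 (Myc) had a median of 0.04 ± 0.03 (SD, n = 5) in Atoh1 carcinomas, chromosome 4 (Taf12, Nfyc and Rad54l) 0.05 ± 0.04, chromosome 6 (Atoh1) 0.07 ± 0.05 and chromosome 10 (Fabp7) −0.04 ± 0.11. Chromosome 6 was gained in part in Atoh1 carcinomas 2 and 5. In Atoh1 carcinoma 2 chromosomes 4 and 11 were also gained in part and chromosome 10 was lost in part (24.4% of its windows). With mode centring the gain in Atoh1 carcinoma 5 and the loss of chromosome 10 were called, and the gains of chromosomes 4, 6 and 11 in Atoh1 carcinoma 2 were not. The balance in Atoh1 carcinoma 2 turned from 5 autosomes with losses and 7 with gains to 8 and 1, with losses of chromosomes 5, 9 and 18 added. Mode centring also added a loss of chromosome 5 in Atoh1 carcinoma 4, whose gain of part of chromosome 18 was no longer called, and a loss of chromosome 2 in Atoh1 carcinoma 5.

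On chromosome 11, which also carries Trp53, the log2 ratio dropped over 4 neighbouring probes from 69397121 to 69402566 (mm9), a span of 5446 bases, in each of 5 Atoh1 carcinomas. The median of these probes was −3.47 ± 0.54 (SD, n = 5), a difference of −3.31 from papillomas (two-sided exact permutation p = 0.00794, the smallest possible, adjusted 0.0159). With normexp correction the difference was −1.36 and with probes well above background only it was −1.26. The intact neighbours ended at 69395425 and began again at 69404685. Depth is poorly measured here, because the tissue signal of 3 of the 4 probes was not well above background in at least 4 of 5 carcinomas. At the probe at 69398736, where it was so in all 5, the ratio was in the group mean at least 5.71-fold lower than in papillomas. The probe at 69400540 stayed well above background in every carcinoma and read −1.13 ± 0.04 (SD, n = 5), beside −0.12 ± 0.14 in papillomas.

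**Figure D2:**
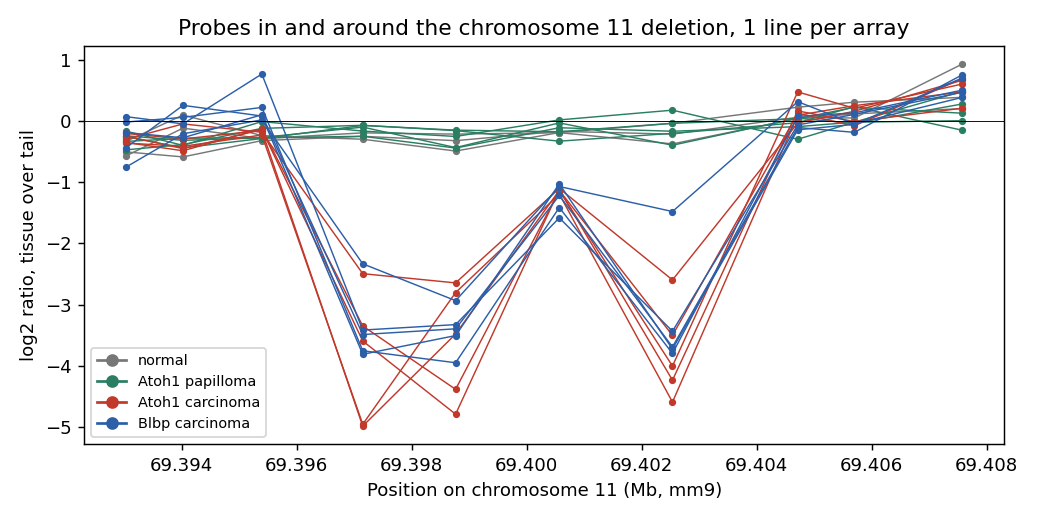
Log2 ratio of single probes against their position on chromosome 11 (Mb, mm9), 1 line per array, coloured by group. The 4 probes from 69397121 to 69402566 drop in all 10 carcinomas and in none of the 8 other arrays, and that at 69400540, the only one well above background in all 10, has a mean of −1.13 in Atoh1 and −1.26 in Blbp carcinomas.

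In Atoh1 carcinomas the altered genome share was 14.7% ± 6.23 (SD, n = 5), 14.0 percentage points above papillomas (two-sided exact permutation p = 0.00794, the smallest possible, adjusted 0.0159). With limma, chromosome 8 was lower by −0.38 (SE 0.12, adjusted p = 0.0400), chromosome 12 by −0.36 (SE 0.12, adjusted p = 0.0400) and chromosome 19 by −0.34 (SE 0.07, adjusted p = 0.0228). Another 7 autosomes (1, 4, 6, 7, 11, 15 and 17) were higher by 0.03 to 0.07. An exact permutation test per autosome also called 10, with chromosome 14 in place of chromosome 12 (adjusted p = 0.0823). Of 852 windows called, 779 were lower, of which 357 lay on chromosome 8 and 417 on chromosome 19, and 73 were higher. With mode centring 995 were called, 986 lower and 9 higher. The largest differences were −0.62 on chromosome 8 (SE 0.11, windows starting at 22100001 and 111000001), and the largest positive one was 0.52 at 93100001 on chromosome 7 (SE 0.05, adjusted p = 0.0171).

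The share difference was 24.2 points with normexp correction and 27.7 points at a threshold of 0.1. With mode centring only chromosome 19 was called. Chromosomes 8 and 12 then missed the threshold with larger differences of −0.43 and −0.41 (adjusted p = 0.0548 each by limma), whereas those of chromosomes 1, 7 and 15 were −0.02, −0.00 and −0.00. Without any one papilloma 0 autosomes passed, with 0 or 1 window. The losses stayed about as large when any one array was left out, at −0.45 to −0.30 for chromosome 8, −0.47 to −0.29 for chromosome 12 and −0.41 to −0.29 for chromosome 19 (adjusted p at most 0.0884). Scan days split the groups unevenly. On the first day the altered genome share was 15.9% in 4 carcinomas and 0.724% in 1 papilloma, and on the second 9.82% in 1 carcinoma and 0.640% in 4 papillomas. The deletion differed by −3.35 and −3.50 on these days, chromosome 8 by −0.45 and −0.12, chromosome 12 by −0.29 and −0.65, and chromosome 19 by −0.35 on both. With the scan day as a block, the share differed by 12.2 points and the deletion by −3.42 (exact permutation p = 0.04 each, the smallest possible), whereas limma called 0 autosomes and 0 windows, with 3003 windows at an unadjusted p under 0.05. The differences in that fit were −0.28 for the chromosome 8 median log2 ratio, −0.47 for chromosome 12 and −0.35 for chromosome 19.

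**Figure D3:**
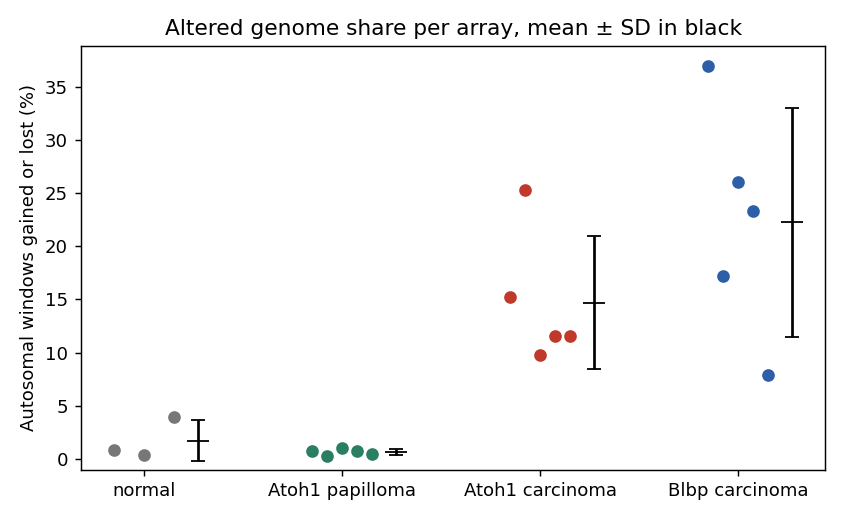
Percent of autosomal windows gained or lost (vertical axis) in each array, by group, with the mean and SD in black. Papillomas lie between 0.274% and 1.08%, Atoh1 carcinomas between 9.82% and 25.3% and Blbp carcinomas between 7.90% and 37.0%.

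The third comparison set carcinomas of the Blbp-Cre line against papillomas. Blbp carcinomas had between 2 and 7 called autosomes each. Chromosome 19 was lost as a whole in 3 of 5 (Blbp carcinomas 3, 4 and 5, at −0.80, −0.53 and −0.53), chromosome 8 as a whole in 2 (Blbp carcinomas 4 and 5, at −0.73 and −0.61) and distal chromosome 12 in 2 (Blbp carcinomas 3 and 4). Chromosome 6, which carries Atoh1, Ccnd2, Braf and Met, was gained in 3 of 5, as a whole in Blbp carcinomas 1 and 3 (0.41 and 0.42) and from 90.3 to 149.6 Mb at 0.75 in Blbp carcinoma 2. Chromosome 1 was gained in Blbp carcinomas 1 and 2 (0.28 and 0.34), and chromosome 16 as a whole in Blbp carcinoma 4 (0.53) and over most of its length in Blbp carcinoma 2, which had lost its distal end.

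In Blbp carcinoma 1 the direction depended on the centring. Its most frequent window value lay at −0.205 relative to its median. With median centring it had losses of chromosomes 4, 7, 9 and 18 and of part of chromosome 8, with medians from −0.26 to −0.20, and gains of chromosomes 1 and 6. With mode centring it had 0 losses and 10 gained autosomes, chromosomes 1 and 6 among them.

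Blbp carcinomas had the drop on chromosome 11 too, at −3.22 ± 0.75 (SD, n = 5), a difference of −3.07 from papillomas (two-sided exact permutation p = 0.00794, the smallest possible, adjusted 0.0159). With normexp correction the difference was −0.62 and with probes well above background only it was −1.11. The probes at 69397121, 69398736 and 69402507 were not well above background in any of them. In the group mean this leaves ratios at least 2.08, 2.28 and 2.25-fold lower than in papillomas. The bound is weaker in Blbp carcinoma 5, at no more than 77.6%, 51.7% and 57.2% of the tail value. The probe at 69400540 was well above background and read −1.26 ± 0.23 (SD, n = 5). Chromosome 15 (Myc) had a median of 0.03 ± 0.04, chromosome 4 −0.06 ± 0.12 and chromosome 10 (Fabp7) −0.04 ± 0.15. Chromosome 10 was lost as a whole in Blbp carcinoma 4, at −0.28.

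Their altered genome share was 22.3% ± 10.8 (SD, n = 5), 21.6 percentage points above papillomas (two-sided exact permutation p = 0.00794, the smallest possible, adjusted 0.0159). At a threshold of 0.1 the difference was 14.7 points (adjusted p = 0.455 by exact permutation), and papillomas alone then had shares of 6.76% to 20.8%. With limma 0 autosomes differed and 3 had an unadjusted p under 0.05. The differences were 0.23 for chromosome 6 (SE 0.08, adjusted p = 0.151), −0.38 for chromosome 19 (SE 0.12, adjusted p = 0.151) and −0.32 for chromosome 8 (SE 0.13, adjusted p = 0.242). Limma called 294 windows on 17 chromosomes, 251 of them lower, beside 42 with mode centring. The window with the largest difference, −1.85 at 36300001 on chromosome 16 (SE 0.15, adjusted p = 0.00276), stood at 0.03 with probes well above background only, and −1.59 at 71000001 on chromosome 11 (SE 0.31) stood at 0.20 with normexp correction. Leaving out any one papilloma left 1 or 2 windows. All Blbp carcinomas were scanned on a day of their own, with the lowest signal over background of the groups and tail DNA of other codes. Scan day, tail DNA and group therefore cannot be told apart.

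**Figure D4:**
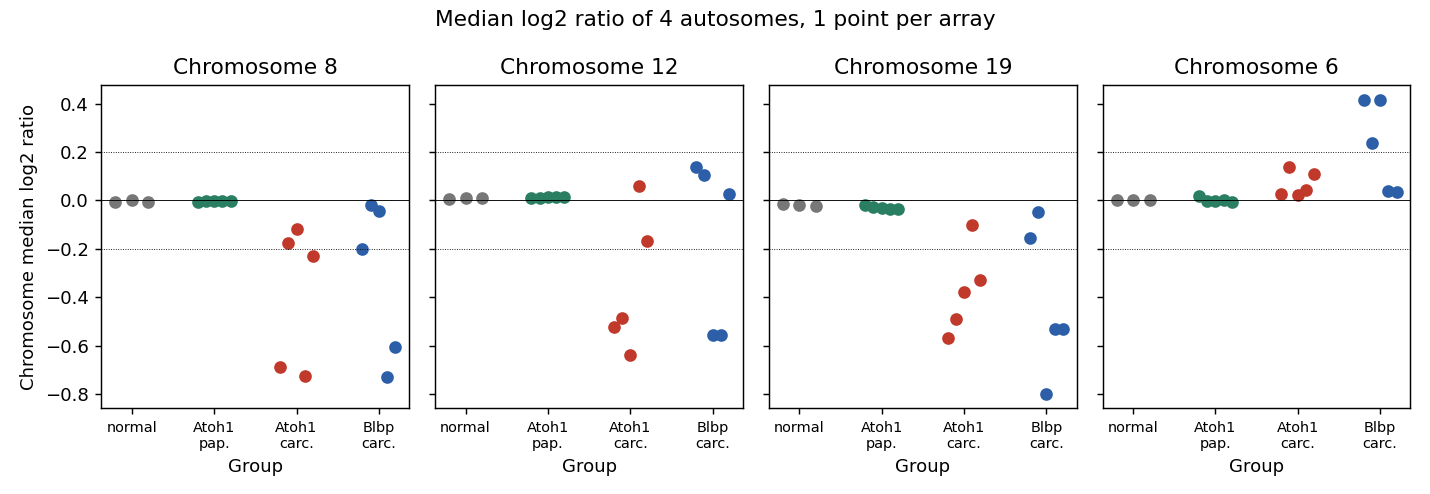
Median log2 ratio of chromosomes 8, 12, 19 and 6 (vertical axis), 1 point per array, by group, with dotted lines at 0.2 in size. Normal tissues and papillomas lie between −0.04 and 0.02, Atoh1 carcinomas reach −0.72 on chromosome 8, and 3 Blbp carcinomas lie between 0.24 and 0.42 on chromosome 6.

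The fourth comparison asked whether carcinomas of the Cre lines differed. Losses of chromosomes 8, 12 and 19 occurred in both. Of all 10 carcinomas, 9 had lost at least 1 of these chromosomes, 7 had lost more than 1 and 5 had lost all 3. These counts were 8, 7 and 5 with mode centring. Blbp carcinoma 2 had lost none of them. Gains of whole chromosomes 1, 6, 7, 9 and 16 were seen in Blbp carcinomas, and the only whole chromosome gained in Atoh1 carcinomas was chromosome 14 in Atoh1 carcinoma 2. Whether gains were more frequent in 1 line was not tested.

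The altered genome share differed by 7.59 percentage points (two-sided exact permutation p = 0.222, adjusted 0.222), and by −4.18 with normexp correction and −13.0 at a threshold of 0.1. The deletion differed by 0.24 (exact permutation p = 0.524, adjusted 0.524), and by −0.09 without Blbp carcinoma 5. With normexp correction it differed by 0.74 (adjusted p = 0.0106 by exact permutation). As 3 of the 4 probes were not well above background in at least 9 of the 10 carcinomas, neither value measures a difference in depth. With limma 0 of 19 autosomes differed, and 0 had an unadjusted p under 0.05. The differences were 0.16 for chromosome 6 (SE 0.08) and 0.24 for chromosome 16 (SE 0.13), each with an adjusted p of 0.4655. Limma called 37 windows, 33 of them lower in Blbp carcinomas, and 0 with mode centring, where 3889 had an unadjusted p under 0.05. Without Atoh1 carcinoma 4 the balance turned, with 389 windows called, 238 of them higher. The largest were −1.65 at 36300001 on chromosome 16 (SE 0.20), which stood at 0.07 with probes well above background only, and 1.35 at 46800001 on chromosome 9 (SE 0.19). Scan day, tail DNA and group cannot be told apart here either.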

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

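The tests that weigh explanations in this part were all chosen after the values had been seen. Within groups of 5 arrays, 6 of 42 sets of values held an array far from the others by Dixon's test, and chance marks about 1 in 20 groups.

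Atoh1 carcinoma 2 stood apart from the other Atoh1 carcinomas on 4 of the chromosomes tested. Not all autosomes were tested this way, and chromosome 14, gained in this tumour at 0.32, was left out. The median of Atoh1 carcinoma 2 was −0.47 on chromosome 16, where the others lay between 0.02 and 0.05. It was 0.12 on chromosome 4, 0.11 on chromosome 11 and 0.12 on chromosome 17. These 3 values depend on the centring, since the most frequent window value of this array lay 0.09 above its median. With mode centring no gain of chromosomes 4, 11 or 17 was called in it. The median of chromosome 6 in papilloma 1 was 0.0164, and the other papillomas lay at −0.00. Blbp carcinoma 5 read −1.91 over the deletion on chromosome 11, where the other Blbp carcinomas lay between −3.78 and −3.37. The tissue signal of 3 of the 4 probes was not well above background in any Blbp carcinoma, so this value does not measure a smaller loss. At the remaining probe, at 69400540, Blbp carcinoma 5 read −1.07, within the range of −1.58 to −1.03 of the others.

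In Atoh1 carcinoma 2 the losses were also of unequal depth, with −0.18 on chromosome 8 and −0.49 on chromosome 19. Only 23.4% of the windows of chromosome 8 were called lost in this tumour. The difference of 0.31 is the pattern itself, so it does not show whether admixed cells without the losses were present. Such cells would dilute all losses alike, so alone they would not make the losses unequal. A bias between the chromosomes on all arrays is argued against, since the largest such difference in the 8 normal and papilloma arrays was 0.0359. A loss carried by part of the tumour cells, or a start from unequal copy numbers, may contribute to the difference, and these were not told apart.

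The Y chromosome, outside the comparisons of this study, had ratios larger in size than in any normal tissue on 3 arrays. Atoh1 carcinoma 3 read 1.52 and Blbp carcinoma 5 read 2.40, both against a female tail reference. There 38.8% and 2.44% of Y probes were well above background in the tissue, and 22.2% and 2.03% in both channels. All 7 tumours with a female reference spread from 0.06 to 2.40, so these values do not show a change of the Y chromosome. Blbp carcinoma 2 read −2.01 against a male reference, where the other 7 tumours with a male reference lay between −0.01 and 0.23.

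For Blbp carcinoma 2, a female tumour with both X chromosomes set against a male reference would raise the X chromosome by the step of 0.59 seen between normal tissues of low and high Y ratio. Its X median was 0.0309, which argues against that explanation. Dim signals on the Blbp arrays are argued against as well, since at least 77.0% of Y probes were well above background in the other Blbp carcinomas with a male reference, beside 3.86% in this one. Loss of the Y chromosome in a male tumour may explain the ratio, and a female tumour that lost an X chromosome was not excluded. The labels do not give the sex of the tumour, and no biological explanation was tested.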

How the results depend on the processing

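The scan-day permutation of the deletion and the altered genome share was chosen after the data had been seen, as were the counts of gained and lost autosomes with mode centring, and the other alternatives before. The carcinoma differences in the deletion kept their direction in every alternative and their call in all but the replicate block, where −3.31 and −3.07 had adjusted p = 0.125, and so had the shares of 14.0 and 21.6 points. With 5 pairs that exact test cannot go below 0.0625, and replicate numbers did not pair the samples by correlation. Leaving out each replicate gave −3.54 to −3.20 and −3.40 to −2.93 for the deletion, and 11.4 to 15.2 and 17.9 to 25.2 points for the share. It gave 0.04 to 0.08 for the deletion and −1.76 to 0.0231 points for papilloma against normal, and −0.0863 to 0.47 and 3.92 to 11.2 points for Blbp against Atoh1 carcinoma. Blbp carcinoma 5 and normal replicate 3 alone turned the direction. Normexp correction gave a deletion difference of 0.74 between the carcinomas (adjusted p = 0.0106 by exact permutation) and a share of −4.18 points. A threshold of 0.1 gave 14.7 points for Blbp carcinoma against papilloma (adjusted p = 0.455 by exact permutation) and −13.0 between the carcinomas. That threshold also marked arrays without a called autosome, with shares of 6.76% to 20.8% in papillomas and 6.05% to 30.8% in normal tissue. A threshold of 0.3 gave 0.0148 points for papilloma against normal. The cause was not tested.

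Counts of windows and autosomes moved most. Leaving out each replicate gave 2 to 9, 0 to 2255, 1 to 1264 and 0 to 389 windows in the 4 comparisons, and 0 to 2, 0 to 13, 0 to 1 and 0 to 0 autosomes. For windows in papilloma against normal, normexp gave 11, probes well above background 3, all groups in one fit 0, the replicate block 8 and the scan day as a random block 140. For Atoh1 carcinoma against papilloma, all groups in one fit, the replicate block and the scan-day block each gave 0, with 3223, 4621 and 3003 at an unadjusted p under 0.05. For Blbp carcinoma against papilloma the counts were 820 with normexp, 42 with the mode, 474 with probes well above background, 2592 with all groups, 1 with the replicate block, 50 with the reference sex and 15031 with the random scan day. Between the carcinomas they were 12, 0, 56, 2804, 1, 0 and 9913 in the same order. The random block is no usable fit, since the fitted correlations within a day were −0.14, −0.24 and −0.23 while the days coincide with groups.

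For autosomes, normexp gave 2 in papilloma against normal. In Atoh1 carcinoma against papilloma, 1 remained with the mode (0 higher and 1 lower, against 7 and 3, with chromosomes 8 and 12 at −0.43 and −0.41 and adjusted p = 0.0548), 2 with the reference sex as a block, and 0 with all groups, the replicate block or the scan-day block. All groups gave 2 and the random scan day 11 in Blbp carcinoma against papilloma, and the random scan day 4 between the carcinomas. Chromosomes 1, 7 and 15 turned to −0.0212, −0.00200 and −0.00170 with the mode (adjusted p by limma 0.391 to 0.771). The window at 36300001 on chromosome 16 turned with probes well above background to −0.0597 (papilloma against normal), 0.0309 (Blbp carcinoma against papilloma) and 0.0719 (between carcinomas), where normexp gave 0.33. The window at 71000001 on chromosome 11 turned to 0.20 with normexp. In Blbp carcinomas 95.8% ± 4.75 of probe spots were well above background (SD, n = 5), beside means of 99.7% to 99.8% in the other groups. Of 342 values for named chromosomes under the alternatives, 215 kept direction and side of the threshold, 113 lost the call, 11 gained it and 3 turned, and of 678 for named windows 366, 307, 0 and 5 did so.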

Other observations

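The splits and the tests on centring in this part were chosen after the counts had been seen.

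Several carcinomas carried breakpoints within chromosomes. In Blbp carcinoma 2, chromosome 16 was gained from 7.5 to 83.9 Mb and lost from there to 98.3 Mb (−0.74), and chromosome 12 was gained from 3.1 to 57.3 Mb (0.39). Blbp carcinoma 3 had gained parts of proximal chromosome 12 and lost it from 55.8 to 121.3 Mb (−0.80), and Blbp carcinoma 4 had lost it from 46.9 to 121.3 Mb (−0.73). Blbp carcinoma 3 had also gained the whole of chromosomes 7 and 9 (0.41 and 0.38). Blbp carcinoma 4 had gained chromosome 18 from 3.2 to 29.4 Mb (0.51). The parts of chromosome 8 lost in the most tumours, 8 of 10 carcinomas, ran from 92.2 to 98.3 Mb and from 120.6 to 127.0 Mb. Blbp carcinoma 1 is among these 8 and had 0 losses with mode centring, where chromosome 8 was lost in 5 Atoh1 and 2 Blbp carcinomas. On chromosome 12 the parts lost in 6 of 10 lay between 99.2 and 114.4 Mb. These common parts depend on segments just past the threshold of 0.2 in size, and their limits need not be breakpoints. On chromosome 8 they follow Atoh1 carcinoma 2, at −0.22 and −0.23, and at 127.0 Mb Blbp carcinoma 1, at −0.21. On chromosome 12 Atoh1 carcinoma 5 read −0.21 from 102.9 to 110.4 Mb.

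Recurrent events under 5 Mb that no normal tissue had numbered 11 in papillomas, 24 in Atoh1 carcinomas and 9 in Blbp carcinomas, with neighbouring pieces joined. Single windows or short runs led this list. The window starting at 44800001 on chromosome 16 was gained in 5 of 5 papillomas (0.93) and 5 of 5 Atoh1 carcinomas (0.81), and that at 35500001 was lost in 5 of 5 papillomas (−0.65). The run from 46700001 to 47000000 on chromosome 9 was lost in 5 Atoh1 carcinomas (−0.90) and 3 papillomas (−0.91) and gained in 2 Blbp carcinomas (0.81). Arrays shared tail DNA, with other codes for the Blbp carcinomas. A difference between the tissue and a shared tail DNA could recur over the arrays of a group, and it was not tested. Recurrence in this list therefore need not mark changes that arose in the tumours. The run from 116800001 to 117100000 on chromosome 12 was lost in 4 Atoh1 carcinomas (−0.97) and 3 papillomas (−0.92). The window at 52300001 on chromosome 14 was gained in 5 Atoh1 carcinomas (0.93) and 2 papillomas (0.58), and that at 71000001 on chromosome 11 was lost in 4 Blbp carcinomas (−1.38). Of the 24 in Atoh1 carcinomas, 15 are losses on chromosomes 8, 12 and 19, and most of these are pieces of the larger losses there and not separate events. The longest, joined on chromosome 8 from 52000001 to 62500000 with a mean of −0.37, exceeds 5 Mb as a whole.

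The normal tissues differed on the sex chromosomes. The Y ratio was −0.88, 1.32 and −1.02 in replicates 1, 2 and 3, and the X ratio 0.51, −0.13 and 0.43, all against a mixed tail reference. The step of 0.59 on the X chromosome compares with 1 for a change from 1 to 2 copies without compression of the ratios.

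The 7 autosomes that were higher in Atoh1 carcinomas than in papillomas had a median difference of 0.05 with median centring and 0.00504 with mode centring, where 0 of them passed and 3 were negative. Centring on the median of arrays with large losses may therefore produce these small differences.

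Chance was weighed by regrouping the same arrays. For windows, 1 of 56 splits of papillomas and normal tissues gave as many calls as the real 5, the real split itself, and the highest other count was 3. In Atoh1 carcinoma against papilloma 1 of 100 splits reached the real 852, and in Blbp carcinoma against papilloma 1 of 100 reached the real 294, with a highest other count of 0 in both. Regrouping thus rarely gave as many calls in these 3 comparisons, so the arrays are not interchangeable between the groups. This does not exclude chance for single windows. With carcinomas, mixed groups hold arrays with large losses beside flat papillomas, and their wide spread leaves few calls. In papilloma against normal tissue the groups also differ in scan day and tail reference. For the 10 autosomes called in Atoh1 carcinoma against papilloma, 1 of 100 splits reached the real count, with a highest other count of 0. The limit from the wide spread of mixed groups holds there too. The splits ignore the scan day, and with it as a block 0 autosomes and 0 windows were called in that comparison. The counts are also fragile, although the differences of chromosomes 8, 12 and 19 stayed about as large, since leaving out any one papilloma gave 0 autosomes and 0 or 1 window there, and 1 or 2 windows in Blbp carcinoma against papilloma.

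Between the carcinomas 5 of 100 splits gave at least the real 37 windows, and chance cannot be excluded. The highest of these, 668, set Atoh1 carcinomas 1, 2 and 3 with Blbp carcinomas 3 and 4 against the rest. The 5 carcinomas set together are those with the largest losses of chromosome 12. Their lost segments over 5 Mb on it had means from −0.80 to −0.46. Among the rest, only Atoh1 carcinoma 5 had a called loss there, at −0.21 in a segment of 7.5 Mb. A count so far above the real one may therefore reflect the loss of chromosome 12 rather than the Cre line. Where the 668 windows lie was not tested. Where 0 autosomes were called, in papilloma against normal, Blbp carcinoma against papilloma and Blbp against Atoh1 carcinoma, the splits decide nothing, because all 56, 100 and 100 of them reach 0. The highest other counts were 5, 0 and 2.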
